A study of Mus musculus with 6 samples.

How the data were processed

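RNA of 6 independently grown and harvested cultures of the mouse erythroid line G1E-ER4 was measured on 2-colour microRNA (miRNA) arrays, 3 from untreated cells and 3 from cells given 1e-07 M estradiol for 24 h. G1E-ER4 cells are an erythroid line without its own GATA-1 that carries a form of this transcription factor that estradiol switches on. Per the labels, total RNA was labelled with the Hy3/Hy5 kit of a service provider, each sample in Hy3 and a common reference in Hy5, and the reference was an equal mixture of all 6 samples. No dye swap is described. Groups and replicate numbers were taken from the sample titles, which give the untreated cultures as 0 h. No culture kept for 24 h without estradiol was measured, nor cells without the estradiol-activated GATA-1. Time in culture and other effects of estradiol therefore cannot be told apart from GATA-1 activation.

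The deposited scanner tables hold the foreground and local background intensity of each spot in each channel, not background-subtracted, with spot flags. Scanner, spot-finding software and their settings are not given in the sources used here. Each array holds 2240 spots in 16 blocks, with 294 probes that name a mouse miRNA (275 names, 4 spots per probe) and 170 probes without a named mouse target. The deposited copies of these tables in a second format held the same intensities and flags, with 0 differing cells on every array. In the authors' normalized tables, the deposited ratio of a probe is Hy3 over Hy5 after lowess normalization within the array, per the file headers. It equalled the inverted median of the Hy5/Hy3 ratios of its spots not marked empty for 100% of the probes with a deposited ratio on every array (relative tolerance under 1e-06). Such a ratio was given for between 149 and 217 of 477 probes per array. The deposited log2 values are the log2 of that ratio, and the series' value table held the same log2 values on every array. The medians of its columns were 0.08, 0.04 and 0.09 for untreated replicates 1 to 3, and -0.01, -0.01 and -0.00 for estradiol replicates 1 to 3. Scale and direction follow from this match, and no further centring was found. Its rows carry no probe name that could be matched, so it was not fitted on its own. Over the tested probes, the authors' log2 ratios correlated with those computed here at r between 0.992 and 0.999 (across probes within an array).

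From the scanner tables, mean foreground and median background intensities were corrected with normexp (offset 50), log2(Hy3/Hy5) was normalized within each array by global loess with control spots at weight 0, and the spots of a probe were averaged, with limma 3.58.1 in R 4.3.3. Spots flagged for shape or contamination were left out, between 111 and 212 per array. Spots flagged only because they were saturated were kept, which departs from the rule written beforehand and is compared with it as an alternative. Different probes of 1 miRNA were tested separately, and 19 names had 2 probes. A probe was tested if its Hy3 median exceeded the local background median by 2 background SD in a share of at least 0.5 of its spots, on all 3 arrays of a group. This filter is strict here, since the background SD was 1.28 times the background median (median over miRNA spots), and it left 51 of 294 probes. Their log ratios were compared, estradiol minus untreated, with lmFit and eBayes with an intensity trend, adjusted by Benjamini-Hochberg, at a threshold of 0.05. Lists of miRNAs (20) were tested with camera's formula on the moderated statistics of the same fit, with a preset correlation of 0.01, where at least 3 members were tested, and with fry beside it. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

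The comparisons, lists, threshold, first set of alternatives and the rule for named miRNAs were fixed before the data were examined. That rule takes the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, all measured members of the miR-144 and miR-451 locus, and from every other list with a tested member the 2 with the largest absolute change and the brightest. MiRNAs named only from the test without the brightness filter were chosen after their values were seen. So were miR-503, miR-351, let-7c, let-7d, miR-140, miR-143, miR-542-5p and probe 14284 of miR-422b.

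On arrays simulated for the miRNA comparison (51 probes, 10 of them changed, 10 runs), the procedure recovered 69% of changes of 0.5 on the log2 scale and 96% of changes of 1, with 100% of the recovered ones in the right direction. Of 410 unchanged probe tests it called 5 and 6. These are shares of the unchanged tests and not of the calls, so they do not give the false discovery rate. The simulated noise was set by hand, every probe had signal in both channels, and no difference between the groups' arrays was simulated. The rates of recovery and of false calls therefore need not hold for the real arrays. In simulated lists of independent probes (51 probes, 200 runs), a list of 5 members shifted by 0.5 had an unadjusted camera p under 0.05 in 100% of runs. An unshifted list had one in 3%. The let-7, stem and early progenitor and pluripotent cell lists had estimated correlations of 0.355, 0.227 and 0.058. The 3% therefore does not give the rate of false calls for correlated lists.

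A miRNA that the spot finder called empty in Hy3 on every array of a group has only a bound on its fold there. The bound sets the brighter group's mean Hy3 level against the dimmer group's mean of the higher of the lowest level above background and the probe's own, on log2 levels after loess and quantile normalization of average intensities, and it is open to dye bias. This use of the empty call was chosen after seeing the data. Alternatives covered background correction, normalization within and between arrays, the Hy3 channel alone, the authors' values, spot summary, flags, brightness filters, variance models, a replicate block and each array left out. A block for slide or scan date was not fitted because the tables used here give neither. A fit of mouse probes alone is the fit reported, since every named probe is a mouse one. The number of arrays limits the precision: the median SD between arrays was 0.14 (untreated) and 0.08 (estradiol) on the log2 scale, against 0.11 between the spots of a probe.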

Results

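Mature miRNAs were profiled in G1E-ER4 cells, a mouse erythroid line in which estradiol activates GATA-1, to find miRNAs that change when this regulator of red cell maturation is switched on. Untreated cells at 0 h (3 arrays) were set against cells treated with estradiol for 24 h (3 arrays). Every value is a log2 ratio of the sample to a common reference mixed from all 6 samples. The median Hy3 foreground intensity of miRNA spots was between 1667 and 2261 on the untreated arrays and between 1835 and 1954 on the estradiol arrays. Of 294 miRNA probes, 38, 47 and 40 lay above background by 2 background SD on the untreated arrays and 58, 62 and 57 on the estradiol arrays. Log ratios of the 51 tested probes correlated at 0.955 to 0.967 within the untreated group, 0.978 to 0.988 within the estradiol group and 0.612 to 0.766 between groups (across probes, which are not independent replicates).

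MiR-451, an abundant miRNA of maturing red cells, showed the largest change of the tested miRNAs. Its log ratio was -4.37 ± 0.33 (SD, n = 3) in untreated cells and 0.67 ± 0.11 (SD, n = 3) after estradiol, a difference of 5.04 (SE 0.15; limma adjusted p = 2.3e-09). The spot finder called it empty on every untreated array and above background on all 3 estradiol arrays, so the measured levels bound the rise at at least 8.46-fold. MiR-144, whose gene lies beside that of miR-451 (in assembly GRCm38.p6 only Mir451b lies between them), had log ratios of -1.12, -1.04 and -0.92 in untreated cells and 0.65, 0.57 and 0.24 after estradiol. Its mean log ratio was 1.51 higher, but it did not pass the brightness filter and was not tested there. With all 294 probes tested its limma adjusted p was 1.1e-05 (SE 0.16). The spot finder called it above background on 0 untreated and 2 estradiol arrays, so no fold is given, and the difference was 0.30 when loess was fitted on probes above background in both channels. That loess was fitted on 44 probes, and miR-144 was not among them. The value of 0.30 therefore rests on a curve set by other probes and does not decide how far miR-144 rose.

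**Figure D1:**
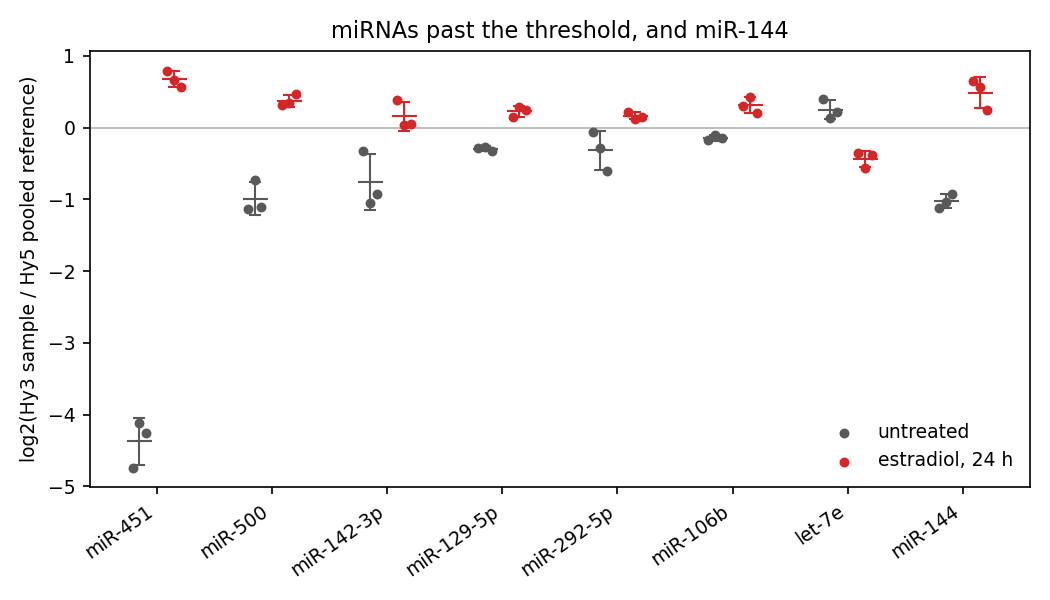
Log2 ratio of sample (Hy3) to pooled reference (Hy5) on the vertical axis for the 7 miRNAs past the threshold and miR-144, untreated in grey and estradiol in red, with points for arrays and bars for the mean ± SD of 3 arrays. MiR-451 moves from -4.37 to 0.67, and the groups do not overlap for any miRNA shown.

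Of 51 tested probes, 7 passed the threshold, 6 higher and 1 lower after estradiol, all with no overlap between the groups. Without overlap were 15 probes (29.4%), where chance gives 10%. Tested probes without a named mouse target were without overlap no less often, among them probes 13131, 14316 and 11130. Their targets are unknown and may themselves respond to estradiol, so they do not show how often other differences between the arrays give this. The share of 29.4% by itself cannot tell an effect of estradiol from another difference between the untreated and the estradiol arrays. MiR-500 rose 2.58-fold (log2 1.37, SE 0.12; limma adjusted p = 1.7e-05). MiR-142-3p, a miRNA of blood cells, rose by 0.92 (SE 0.18; adjusted p = 0.0059), and miR-129-5p rose by 0.52 (SE 0.08; adjusted p = 0.0011) on the log2 scale. The probe of miR-129-3p pointed the other way, at -0.68 (SE 0.25; limma adjusted p = 0.14 without the brightness filter, which it did not pass). The spot finder called it above background on 3 untreated and 3 estradiol arrays. MiR-292-5p rose by 0.48 (SE 0.12; adjusted p = 0.024) and miR-106b by 0.46 (SE 0.10; adjusted p = 0.0092). Let-7e fell by 0.69 (SE 0.10; adjusted p = 0.00072), a 1.61-fold decrease. The call on miR-292-5p ended without any 1 of the 3 estradiol replicates (adjusted p = 0.0983, 0.0931 and 0.0795 without replicates 1, 2 and 3; 5.1e-05 to 0.225 over the alternatives), in the authors' log ratios (adjusted p = 0.0640) and without the intensity trend (adjusted p = 0.0515). That on miR-106b ended without estradiol replicate 1 (adjusted p = 0.0553; 0.00122 to 0.755 over the alternatives) and with loess on probes above background in both channels (adjusted p = 0.272). In Hy3 alone, without the reference, the calls on let-7e (-0.42), miR-142-3p (0.31), miR-129-5p (0.71) and miR-106b (-0.20) ended, and centring on spiked controls ended those on miR-142-3p (0.78), miR-129-5p (0.34), miR-292-5p (0.33) and miR-106b (0.35) and kept let-7e. Median centring ended the calls on miR-129-5p (0.44), miR-292-5p (0.43) and miR-106b (0.45).

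**Figure D2:**
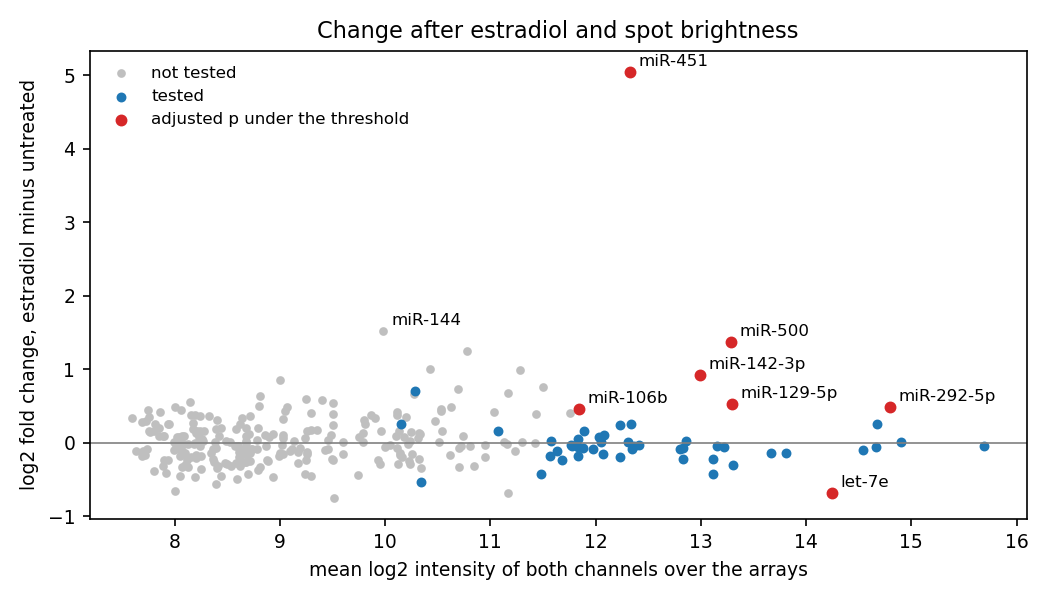
Log2 fold change (estradiol minus untreated, vertical) against the mean log2 intensity of both channels (horizontal) for 294 miRNA probes, with the 7 past the threshold in red, the other tested probes in blue and those not tested in grey. MiR-451 stands at 5.04 and miR-144, not tested, at 1.51.

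Most miRNAs of the erythroid lists were too dim for the brightness filter. With all 294 miRNA probes tested, 19 passed, 17 higher and 2 lower, including the 7 above. The erythroid maturation list had 9 measured probes, of which only miR-185 passed the filter (-0.11, adjusted p = 0.41; 0 passed adjusted over the list alone). Without the filter 2 of the 9 rose, miR-16 (0.99, SE 0.23; limma adjusted p = 0.018) and miR-15b (0.76, SE 0.15; adjusted p = 0.0044), which have neighbouring genes, and 7 did not pass, among them miR-486 at 0.43 (adjusted p = 0.18). In Hy3 alone miR-16 stood at 0.16 and miR-15b at 0.08. Adjusted over the list alone, 2 passed without the filter. Of the 8 probes of miRNAs known to fall on erythroid maturation, none was tested with the filter. Without it miR-222 fell by 0.75 (SE 0.19; adjusted p = 0.027), though it was above background in neither group, and its neighbour miR-221 stood at -0.36 (adjusted p = 0.38). The value of miR-222 ranged from -2.56 to -0.34 over the alternatives. Adjusted over the list alone, 2 passed in opposite directions, miR-222 and miR-103, which was higher after estradiol (0.42; adjusted p = 0.0962 over all probes).

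In the let-7 family, 4 of 9 measured members were tested: let-7e fell, while let-7a (0.26, adjusted p = 0.25; -0.47 in Hy3 alone), let-7c (0.16) and let-7d (0.03) did not pass, and 1 passed adjusted over the list alone. Let-7a passed without untreated replicate 3 (0.31, adjusted p = 0.0457; 0.0457 to 0.646 over the alternatives) and stood at 0.15 without untreated replicate 2. The family's median change was 0.10, its mean -0.06, and camera, which pointed downward, gave an adjusted p of 0.96 (adjusted p = 0.968 with an estimated correlation). Of the miR-17 cluster and its paralogs, 2 of 15 probes were tested: miR-106b rose and miR-17-3p stood at -0.19 (adjusted p = 0.32), with 1 passing adjusted over the list alone. Without the filter 1 of the 15 passed, miR-106b, and the list's median was -0.16. MiR-93 and miR-25, whose genes lie beside that of miR-106b, then stood at -0.10 and -0.27 (limma adjusted p = 0.88 and 0.53). No member of the miR-15/16, miR-29, miR-30, miR-23/27/24 or miR-34 lists passed the brightness filter. Without it 2 of 3 miR-29 probes rose, miR-29a from -0.71 ± 0.18 to 0.29 ± 0.09 (SD, n = 3; limma adjusted p = 0.00052) and miR-29c by 0.86 (adjusted p = 0.0028). The miR-29 family then shifted upward as a set (camera adjusted p = 0.00286), with an adjusted p = 0.326 with an estimated correlation. MiR-29a was above background on 1 array and miR-29c on 0, and their directions turned in Hy3 alone (miR-29a, -0.07) or with loess on probes above background in both channels (miR-29c, -1.07). MiR-29c was not among the probes that this loess was fitted on, so that value does not decide its direction. Of 6 miR-30 probes 1 rose without the filter (miR-30c, 0.74, adjusted p = 0.012; -0.42 in Hy3 alone and -0.15 with that loess). Of 8 miR-15/16 probes 2 rose (miR-16 and miR-15b), and none of 5 miR-23/27/24 and 3 miR-34 probes passed.

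Among markers of other cell types, the myeloid and mast cell list had 7 measured probes and 1 tested, miR-142-3p, which rose. Without the filter 3 of the 7 rose, with miR-21 (1.25, SE 0.17; limma adjusted p = 0.0002) and miR-142-5p (0.67, adjusted p = 0.027) joining it, while the myeloid miRNA miR-223 stood at 0.39 (adjusted p = 0.16). In Hy3 alone miR-21 stood at 0.49 and miR-142-5p at 0.04. In the pluripotent cell list 5 of 16 probes were tested, miR-292-5p rose, miR-290 (0.26, adjusted p = 0.070) did not pass, and 2 passed adjusted over the list alone (camera adjusted p = 0.96, and adjusted p = 0.968 with an estimated correlation). The other tested members stood at 0.02 (miR-291a-5p), -0.05 (miR-291b-5p) and -0.09 (the probe that names both), and the list's median was 0.02. MiR-292-3p, above background in neither group, stood at -0.56 without the filter (limma adjusted p = 0.36). MiR-290 passed without untreated replicate 1 (0.32, adjusted p = 0.0188; 0.0188 to 0.643 over the alternatives). In the stem and early progenitor list none of 3 tested of 10 probes passed, with miR-125a at -0.05 and miR-10a at 0.26. Its median was -0.04, its mean 0.05, and camera pointed downward (adjusted p = 0.96, and adjusted p = 0.968 with an estimated correlation). Neither tested member of the 7 megakaryocyte probes passed (miR-130a at -0.42, adjusted p = 0.11, and miR-10a), nor did miR-214 (-0.15, adjusted p = 0.39), the tested 1 of 6 fibroblast probes. MiR-130a passed without untreated replicate 2 (-0.58, adjusted p = 0.0141; 0.0141 to 0.683 over the alternatives) and stood at -0.26 without untreated replicate 3. Leaving out 1 array moved miR-185 between -0.15 (without untreated replicate 1) and -0.06 (without untreated replicate 3), miR-17-3p between -0.29 (without estradiol replicate 2) and -0.12 (without untreated replicate 1), miR-214 between -0.23 (without estradiol replicate 2) and -0.08 (without untreated replicate 3) and miR-125a between -0.09 (without estradiol replicate 2) and -0.02 (without untreated replicate 2), and none of these passed. The reference signal of miR-10a was empty on all 6 arrays, its direction turned in 4 alternatives, and leaving out 1 array moved its value between 0.04 (without untreated replicate 1) and 0.41 (without untreated replicate 2). The lymphoid (5 probes), muscle (5), neural (6), liver (1) and epithelial (7) lists had no tested member, and none of their probes passed without the filter. With the filter only 3 of the 20 lists had enough tested members for camera (limma), of which 0 passed and 0 had an unadjusted camera p under 0.05. The smallest adjusted p of limma's fry for a shift in 1 direction was 0.767, while its test of change in either direction gave an adjusted p of 0.0182 for the let-7 family. That test can respond to 1 changed member, and of the tested members only let-7e passed by itself, so it does not show a change of the family.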

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

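The tests in this part were chosen after the results they concern were seen. Probes that name no mouse miRNA lie outside the comparison of named miRNAs, and 2 of the 30 that were bright enough to test changed after estradiol when tested on their own. Probe 11115 was not above background on any untreated array and was at least 11.2-fold higher after estradiol (log2 difference 5.69, SE 0.18; limma adjusted p = 1.4e-08). Probe 11086 rose by 0.58 on the log2 scale (SE 0.11; limma adjusted p = 0.012). Tested together with the named miRNAs (81 probes), 3 unnamed probes passed, these and probe 13131 (-0.32; adjusted p = 0.0341, against 0.0507 on their own). The tables used here do not name their targets.

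Probe 11115 followed miR-451. Light from neighbouring spots is argued against, since their spots lay 5 grid steps apart at the nearest. Binding of the same RNA by both probes stays open: their log ratios differed by at most 0.0394 on the estradiol arrays, where the SD between arrays was 0.113, but any RNA nearly absent from untreated cells gives such a ratio against a pool of all samples. On the untreated arrays, where both probes were called empty, probe 11115 differed from miR-451 by -0.58, -0.42 and -0.87, and these differences were not used. A second RNA that is higher after estradiol cannot be told apart from this with these arrays.

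Against an equal pool, a probe's mean sample to reference ratio should lie near 1, and over 81 probes that the spot finder called empty in Hy3 on none of the 6 arrays the median was 1.02. For 10 of them the ratio exceeded 2 on every array, among them miR-140, miR-10a and miR-143, whose reference was called empty on all 6 arrays, so that the size of their ratios (means of 27.7, 14.6 and 7.96 as computed) is not measured; probe 14302, with a reference above background on all 6, had a mean ratio of 4.51. Loess is argued against, since without it their lowest log ratio was 1.46. Signal in the Hy3 dye alone stays open: the reference channel was empty in 80% of their probe and array pairs, against 3.17% for 42 other probes equally bright in Hy3, but probes picked for a high ratio have a dim reference by that choice, so the comparison decides nothing. Light from neighbouring Hy3 landmark spots is argued against for 9 of the 10, whose spots lay at least 2 grid steps from any, and stays open for miR-140, which lies next to such a spot (of 39 other probes next to one, 53.8% were empty in Hy3 on all 6 arrays), and no biological explanation was tested.

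More miRNA probes were above background on the estradiol arrays than on the untreated ones. The reference channel, which holds the same RNA on all arrays, followed: its lowest estradiol count exceeded its highest untreated count by 7 probes (79 against 72), which is consistent with a difference between the arrays in signal over background that does not come from the samples. The foreground was not higher on all estradiol arrays: the median reference foreground intensity was 885, 1291 and 1670 on the untreated arrays and 1172, 1047 and 1054 on the estradiol arrays. These intensities include the background. Its median in the reference channel was 536, 747 and 1183.5 on the untreated arrays and 556.5, 543 and 587 on the estradiol arrays. Which property of the arrays differs was not tested. A larger number of miRNAs present after estradiol stays open, as the share of reference-channel probes also above background in the sample changed by -3.77 percentage points, from 71.6% ± 9.23 (SD, n = 3) to 67.9% ± 4.88 (SD, n = 3).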

How the results depend on the processing

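Alternatives based on the spot finder's empty call, saturated spots, unnamed probes, spiked controls and reference brightness were chosen after seeing the data. MiR-451 (3.50 to 5.30) and miR-500 (1.19 at the lowest) kept their direction in all 27 alternatives and passed wherever tested; miR-451 was not tested where probes had to be above background on all 6 arrays. The count of 7 became 11 without background correction, 4 with median centring, 19 with no brightness filter, 15 with the empty call as filter and 3 when centred on 4 spiked controls. More probes tested (294 and 86) go with 19 and 15, and for the others the cause was not tested. Leaving out 1 array gave 5 to 10. The share of higher calls, 85.7%, was 75% with median centring or with reference signal required on all 6 arrays, 66.7% with spiked controls, robust eBayes or all spots kept, 62.5% with loess on probes above background in both channels or with probes above background on all 6 arrays, and 50% in Hy3 alone. With 1 array left out it lay between 60% (6 higher and 4 lower, without untreated replicate 2) and 87.5% (without untreated replicate 1). The median change of the tested probes, -0.05, was -0.11 with median centring or the authors' values, -0.14 with that loess, -0.21 with spiked controls and 0.13 in Hy3 alone. MiR-144, at 1.51, moved to 0.75 without background correction, 1.33 with median centring, 0.30 with that loess, 0.91 in Hy3 alone, 1.71 in the authors' values and 1.23 with spiked controls. Directions turned with that loess for miR-29c (-1.07), miR-30c (-0.15), miR-140 (-0.53), miR-422b probe 11105 (-1.27), miR-33 (-1.30) and miR-10a (-1.04), and in Hy3 alone for miR-106b (-0.20), miR-29a (-0.0700), miR-30c (-0.42), let-7a (-0.47), miR-17-3p (0.0247), miR-130a (0.27), miR-125a (0.26) and miR-10a (-0.38). MiR-10a also turned with plain background subtraction (-0.18) and in the authors' values (-0.26), and the cause of these moves was not tested. The loess on probes above background in both channels was fitted on 44 probes. These did not include miR-144, miR-29c, miR-30c, miR-422b probe 11105 or miR-33, which failed the brightness filter. Their values with it rest on a curve set by other probes and do not decide their size or direction. Of 3 lists tested 0 passed, against 1 of 18 without the filter (miR-29 family) and 1 of 8 with the empty call as filter (myeloid and mast cell, adjusted p = 0.0224, and adjusted p = 0.683 with an estimated correlation). With the replicate block 8 probes passed, 7 of them as before, but same-numbered arrays did not deviate together (r = 0.0698, -0.109 and -0.124 across probes), so the numbers were not taken as pairs. The series' value table and a slide block were not run. Signal over background limits the results, as 72.0% of kept miRNA spots were called empty in Hy3.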

Other observations

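The tests of the splits of the arrays and of neighbouring genes were chosen after results were seen, the latter after the fold changes of several neighbours. MiR-503 (-0.31, SE 0.09; limma adjusted p = 0.057) and miR-351 (-0.43, SE 0.14; adjusted p = 0.064), which neighbour each other in assembly GRCm38.p6 together with miR-322, had lower means after estradiol and missed the threshold, and were picked here after their values were seen. MiR-503 passed in 7 of 27 alternatives (adjusted p from 0.0140 to 0.455) and miR-351 in 6 of 27 (0.0101 to 0.9999), both without untreated replicate 2 (-0.38 and -0.57), and the value of miR-351 ranged from -0.60 to 0.00. Their neighbour miR-322 stood at -0.08 without the filter (adjusted p = 0.85, above background in neither group), and of the nearby miR-542, miR-542-5p stood at 0.05 and the probes of miR-542-3p at 0.08 and -0.27, the latter above background in neither group. The miR-99b, let-7e and miR-125a genes also lie side by side, yet let-7e fell by 0.69 while miR-125a stood at -0.05 (adjusted p = 0.73; 0.26 in Hy3 alone) and miR-99b at -0.01 without the filter (adjusted p = 0.98). The small nuclear RNA U6, left out of the normalization, had log ratios of 0.05 ± 0.12 (SD, n = 3) untreated and -0.30 ± 0.07 (SD, n = 3) after estradiol on 1 probe, and 0.27 ± 0.17 and -0.23 ± 0.07 on the other; the 3 estradiol arrays lay below the 3 untreated ones on both, under every alternative that measured U6 the difference stayed below 0, and 3 against 3 allow no exact two-sided p under 0.1. The probes of miR-422b went apart without the filter, at -0.22 (probe 14284) and 0.59 (probe 11105, adjusted p = 0.028, above background in neither group, and -1.27 with loess on probes above background in both channels). Probe 11105 was not among the probes that this loess was fitted on, so the value of -1.27 does not decide its direction.

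One hypothesis was that miRNA genes within 10 kb of each other, which may share a transcript, change alike. Over 34 pairs of probes of miRNAs with different numbers in their names, among 86 probes called non-empty on all arrays of a group (81 matched to a gene), the median absolute difference in log2 fold change was 0.197, against a median of 0.301 and a 5th percentile of 0.168 in 10000 shufflings (permutation p = 0.11, one-sided). The pairs did not pass this test, which leaves the question open. The pairs share probes, and so are not independent: many come from miR-300, miR-381, miR-382, miR-134 and miR-485-3p, of which none passed the threshold. The pair of miR-144 and miR-451 was not included, since miR-144 was called above background on 0 untreated and 2 estradiol arrays.

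Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called probes as the real one, itself, with 7. The highest count of the other splits was 0. Each of these mixes untreated and estradiol arrays in both of its groups, so probes that differ between the real groups spread more within them. A low count there therefore does not argue against chance. With 10 splits no share under 0.05 can be reached.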
